A study of Homo sapiens with 6 samples.

How the data were processed

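Gene expression was measured by sequencing of poly(A)+ RNA from 6 libraries of Mono-mac-6 cells. Per the series' design text, lentiviral guides were delivered to a single Cas9 clone, and cells were selected with blasticidin (10 µg per ml) and hygromycin B (200 µg per ml) for 1 to 2 weeks. The labels give harvest at 8 days after infection, which the longer selection time does not allow, so the day of harvest is uncertain. Groups were taken from the labels, as sgNS (control guide), sgDDX6.1 and sgDDX6.2, with 2 libraries each.

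The table the authors deposited holds TPM, transcript abundance scaled to a fixed total per library, with 2 decimals for each gene and library. Per the submitters' processing notes, RSEM 1.2.31 and GRCh38 were used; the aligner, the gene annotation and the sequences of the guides are not given in the sources used here. TPM divides by transcript length and scales each library to 1000000, which every column summed to, so a value is a share of the library: a rise of abundant genes lowers all others, and depth is unknown. No interval or detection limit that needs counts was therefore given. RSEM divides reads that fit several genes by its model, so genes with near-identical copies are less certain. Of 18806 symbols, 18644 (99.14%) were found in GENCODE release 29 (GRCh38), directly or by an older name. It served for coordinates and transcript properties, and may not be the annotation the authors used. Genes listed at 0 in every library numbered 3145.

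From these values log2(TPM + 1) was computed, and genes with a TPM of at least 1 in 2 or more libraries were kept, 11151 in all. A linear model with 3 group means was fitted to all 6 libraries with limma 3.58.1 in R 4.3.3 (3 residual degrees of freedom, variance trend on mean expression), and contrasts were taken for the mean of both guides minus sgNS, each guide minus sgNS, and sgDDX6.2 minus sgDDX6.1. Tests were two-sided, with Benjamini-Hochberg adjustment over genes within each contrast and a threshold of 0.05. A fold change in the text is on the log2(TPM + 1) scale, which understates the change of low genes. No group had more than 2 libraries, so regrouping the libraries was not used as a test.

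Gene lists, the design, the rule for named genes and the alternatives were fixed before the data were examined. Of 41 lists, 34 had at least 5 tested members. They cover amino acid, lipid, mitochondrial and sugar metabolism, stress and interferon responses, leukemia and monocyte identity, translation, RNA granules, the cell cycle, cell death and drug handling. Lists for other cell types and for class II antigen presentation had fewer, and are given as values. The lists of mitochondrial genome mRNAs and of RNAs without a poly(A) tail had 0 members in the table and were not analysed here. Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which tests whether a list's genes move on balance in a single direction and does not compare them with other genes; p-values were adjusted over lists. Beside the count of members past the threshold over all genes, a count adjusted over the list alone was made. Lists of heat shock chaperones, ER chaperones, tRNA synthetases and other TOP mRNAs were added after the data were seen, and adjusted among themselves.

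DDX6 is named first. For both guides against sgNS, the 12 genes with the largest log2 fold change in each direction are named, among genes with an adjusted p under 0.05, a mean TPM of at least 5, and all 4 sgDDX6 libraries on the same side of both sgNS libraries. For sgDDX6.2 against sgDDX6.1, the 5 in each direction are named by the same rule. From each list described with member values, up to 4 members with the lowest adjusted p are named. These are the lists called by camera and 4 others, of processing bodies, glycolysis, apoptosis and the MLL-fusion program, which were chosen for description after the results were seen. Some genes that the rule selects are not reported here. Genes named outside this rule were chosen after their values were seen. They are ATF4, DDIT3, BST2, genes of lists with too few tested members, genes of the lists added later, and those described under other observations.

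Both guides share the sgNS libraries. The value expected without any effect was taken from 100 simulations in which 3 unchanged groups were drawn around each gene's mean over all libraries with its fitted spread. Alternatives were pseudocounts of 0.1 and 5, no filter and a TPM filter of 5, quantile normalization, and median centring. Others were limma without the trend or with robust estimation, the replicate number in the model, leaving out each library, fitting only the groups compared, and treating the 4 sgDDX6 libraries as a single group. Alternatives added after the data were seen were the removal of a loess trend on transcript GC content from each library, and lists without members of the ATF4 list.

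The procedure was also tested on simulated data. In 10 simulated sets of all 11151 genes for the comparison of both guides with sgNS, 200 genes were changed; of those changed by 0.25, 0.5 and 1 on the log2 scale, 65.1%, 98.8% and 100% were recovered, and 6.6% of calls were false. A list of 30 genes moved by 0.5 was called by camera in 10 of 10 simulations and an unmoved list in 0. With an estimated correlation, camera also called the moved list in 10 of 10 and the unmoved list in 0. These simulated calls were not adjusted over 34 lists, as the calls in the data were. The simulated sets had 200 changed genes, whereas 7434 of 11151 genes passed the threshold in the data. How often camera would call a moved list in the data was thus not measured, with either the preset or the estimated correlation. Lists whose genes vary together were not simulated, although the estimated correlation reached 0.64 for cytosolic ribosomal proteins in the data. The simulations therefore cannot gauge false calls of such lists. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.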

Results

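Poly(A)+ RNA of Mono-mac-6, a human acute myeloid leukemia (AML) line with monocytic features that carries the MLL-AF9 fusion gene, was sequenced after a CRISPR guide was delivered to a single Cas9-expressing clone. The guides were sgNS, a control guide, and sgDDX6.1 and sgDDX6.2, which both target DDX6, a DEAD-box RNA helicase of processing bodies that takes part in mRNA decay and translational repression. Each of the 3 groups had 2 libraries, 6 in all, harvested 8 days after infection per the labels, although the stated length of selection leaves this day uncertain. The title of the series places the study in metabolic plasticity and drug resistance of AML, so gene lists for metabolism, stress and drug response were set beside lists for RNA decay, leukemia identity and the cell cycle. The values were TPM for 18806 gene symbols, which carry no read depth. Between 10794 and 11007 genes reached a TPM of 1 or more in a library, and the 20 most abundant genes held between 13.31% and 13.62% of the TPM in each library. Replicates of a group had Pearson correlations of 0.998 across genes, which are not independent replicates. Correlations lay between 0.969 and 0.975 for sgNS with sgDDX6 libraries and between 0.992 and 0.993 for libraries of the 2 DDX6 guides. The first principal component held 76.7% of the variance and separated sgNS from all 4 sgDDX6 libraries, and the second held 16.2% and separated the 2 DDX6 guides.

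DDX6 itself was examined first, since it checks the labels. DDX6 (chromosome 11, 118747766 to 118791149 in GRCh38, a protein-coding gene in GENCODE release 29) had 100.8 ± 1.85 TPM in sgNS, 53.2 ± 1.73 in sgDDX6.1 and 52.9 ± 0.799 in sgDDX6.2 (mean ± SD, n = 2 each). Its log2 fold change over both guides was -0.91 (SE 0.04), with a limma adjusted p of 4.61e-09, and both sgNS libraries lay above all 4 sgDDX6 libraries. With single guides the log2 fold change was -0.91 and -0.92, and the guides differed by -0.01 (adjusted p = 0.918). The 6 libraries thus parted by this gene into sgNS and sgDDX6 as labelled, and the gene does not tell the 2 DDX6 guides apart. A guide cuts DNA, and remaining mRNA is no measure of the protein.

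**Figure D1:**
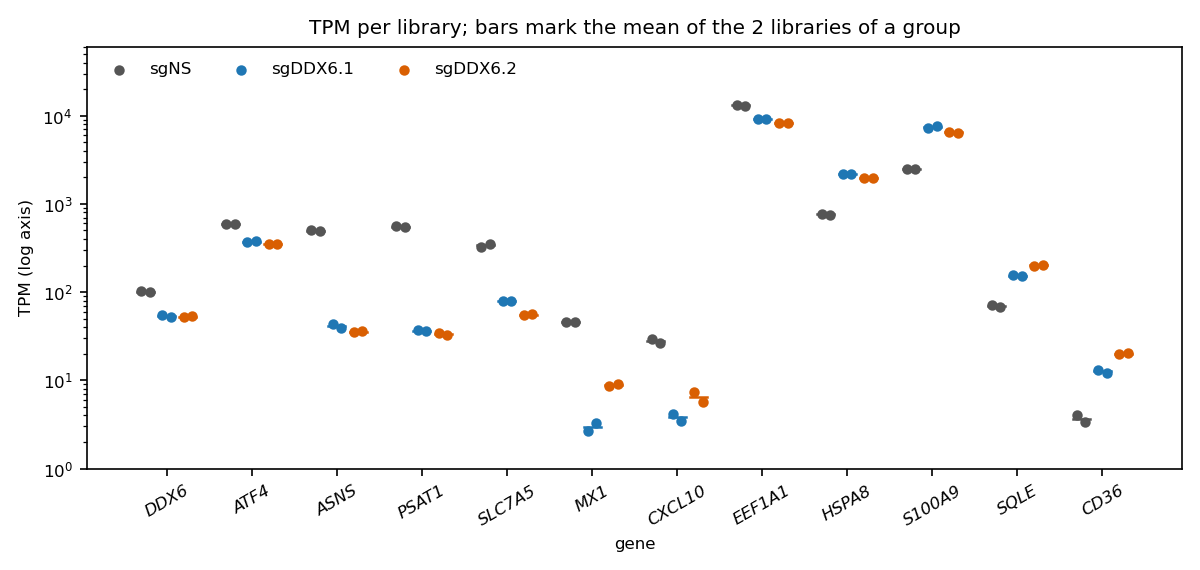
TPM of 12 genes in each of the 6 libraries on a log axis, by guide; points are libraries and bars the mean of the 2 libraries of a group. DDX6 had 100.8 TPM in sgNS and 53.2 and 52.9 with the 2 DDX6 guides, while ASNS went from 496 to 41.2 and 35.5 and S100A9 from 2485 to 7405 and 6454.

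Averaged over both guides, the largest decreases were those of STC2, CHAC1, GDF15 and ALDH1L2. STC2, a secreted glycoprotein induced by stress, had 45.6 ± 0.707 TPM in sgNS, 0.62 ± 0.06 in sgDDX6.1 and 0.19 ± 0.13 in sgDDX6.2 (SD, n = 2), a log2 fold change of -5.07 (SE 0.09). CHAC1, which degrades glutathione, had a log2 fold change of -4.83, the stress cytokine GDF15 -4.59 and the mitochondrial folate enzyme ALDH1L2 -4.25. PSAT1 and PHGDH, enzymes of serine synthesis, had -3.94 and -3.52, TRIB3 -3.94, asparagine synthetase (ASNS) -3.66 and ADM2 -3.57. The calcium-binding protein S100P had -3.79, the chaperone CLGN -3.73 and the homeobox gene DLX2 -3.66. The largest increases were smaller. The hypoxia-inducible factor EPAS1 rose by 2.01 (SE 0.08), from 1.87 TPM to 11.5 ± 0.933 and 9.63 ± 0.658. The fatty acid receptor CD36 rose by 1.87, the chitinase-like protein CHI3L1 by 1.86, the chemokine receptor CCR2 by 1.85, GPNMB by 1.80 and haptoglobin (HP) by 1.77. GPR183 rose by 1.74, SLC29A4 by 1.74, WNT7B by 1.71, SECTM1 by 1.66, DEFB1 by 1.65 and MS4A6A by 1.62 (SE of 0.04 to 0.10).

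Of 11151 genes tested, 7434 (66.67%) passed an adjusted p of 0.05 with limma and Benjamini-Hochberg adjustment, 3764 of them higher and 3670 lower with DDX6 targeted. Most changes were small: 380 of the 7434 genes changed at least 2-fold, 113 up and 267 down. Over all 11151 genes tested, called or not, the median size was 0.23 on the log2 scale. In 6599 of the 7434, all 4 sgDDX6 libraries lay on the same side of both sgNS libraries. The labels do not say that the 2 libraries of a group came from separate cultures, so these p-values measure only the spread between these samples, which may be technical. The count at 2-fold depends on the pseudocount, with 610 genes at 0.1 and 209 at 5, since fold changes on the log2(TPM + 1) scale understate the change of low genes.

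Of 34 gene lists tested, camera with its preset correlation called 17, 8 up and 9 down. No list was called with an estimated correlation, by which 6 passed an unadjusted p of 0.05, and fry called 27. For interferon-stimulated genes the estimated correlation was 0.012, near the preset 0.01, yet the unadjusted camera p went from 4.18e-15 to 0.00456. For cytosolic ribosomal proteins the estimated correlation was 0.64. With an estimated correlation camera tests on the 3 residual degrees of freedom of the fit, and with the preset on far more. For interferon-stimulated genes this difference, rather than correlation between genes, accounts for most of the loss. A call lost with an estimated correlation therefore does not by itself show that correlation between genes explains a list's change. With 3 degrees of freedom a call over 34 lists is hard to reach, so its absence says little. Counts of members are over all genes tested; adjusted over the list alone they were the same in all but 4 lists, where both are given.

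**Figure D2:**
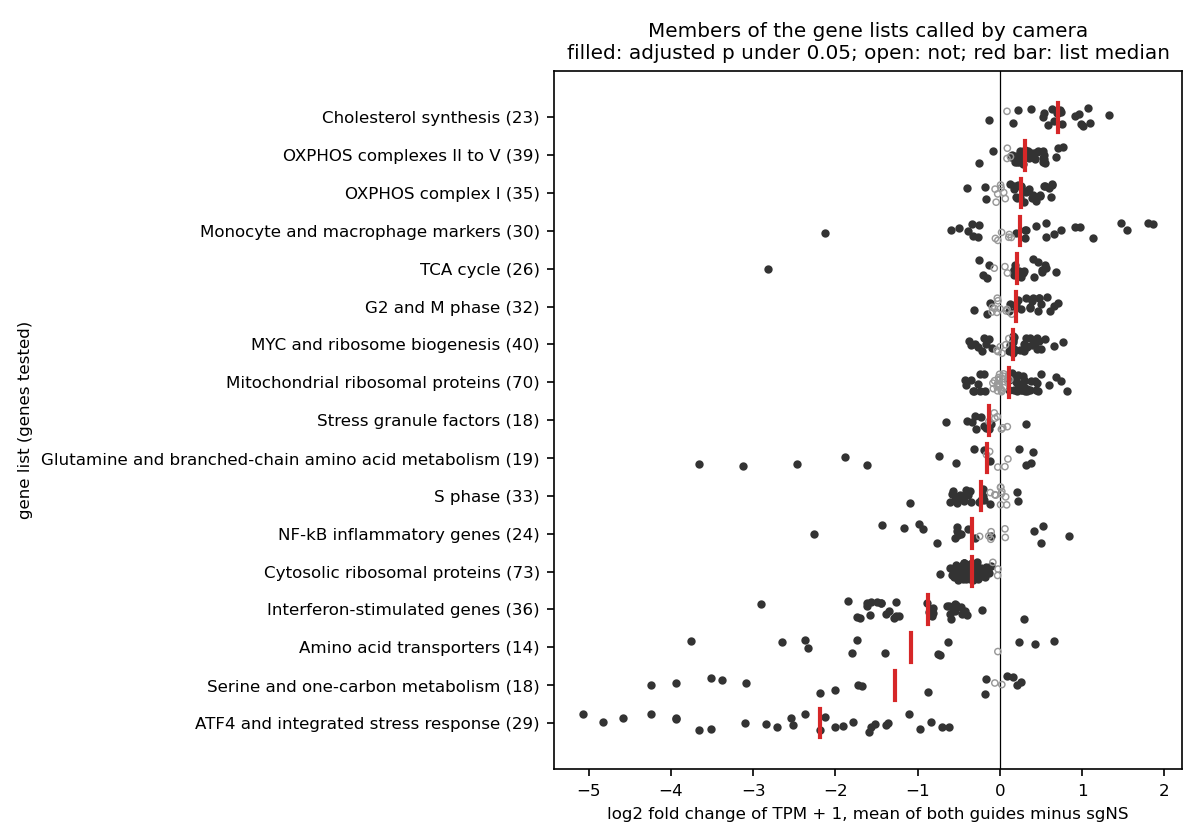
Log2 fold change of every tested member of the 17 gene lists called by camera, mean of both guides minus sgNS; filled points passed an adjusted p of 0.05, open points did not, and red bars are list medians. All 29 members of the ATF4 list lie below 0 with a median of -2.19, and 21 of 23 cholesterol synthesis genes are filled points above 0.

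The list of ATF4 and integrated stress response genes, which serve amino acid supply and the response to translational stress, fell as a whole. All 29 tested members fell, 25 of them at least 2-fold, with a median log2 fold change of -2.19 (camera adjusted p = 1.76e-23, adjusted p = 0.0937 with an estimated correlation). PSAT1 had 553 ± 13.9 TPM in sgNS against 36.6 ± 0.212 in sgDDX6.1 and 33.5 ± 1.05 in sgDDX6.2 (SD, n = 2). PHGDH had 422 ± 13.2 against 35.4 ± 0.721 and 36.5 ± 0.04. TRIB3 had 543 ± 23.2 against 37.4 ± 1.55 and 31.9 ± 1.62, and ASNS 496 ± 6.63 against 41.2 ± 2.92 and 35.5 ± 0.785. ATF4 itself, a transcription factor mostly regulated at translation and singled out after its value was seen, fell by 0.70, from 588 ± 1.52 TPM to 374 ± 10.9 and 350 ± 2.28, and DDIT3, which encodes the stress factor CHOP and was chosen in the same way, fell by 1.59.

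Neighbouring lists of amino acid metabolism went the same way in part. Of 18 serine and one-carbon genes, 12 fell and 4 rose (median -1.27, camera adjusted p = 3.76e-05, adjusted p = 0.187 with an estimated correlation). CBS, which makes cystathionine, fell by 3.09 beside PSAT1, PHGDH and ALDH1L2. Of 14 amino acid transporters, 10 fell and 3 rose (median -1.08, camera adjusted p = 0.000105, adjusted p = 0.329 with an estimated correlation). The leucine transporter SLC7A5 went from 340 ± 16.6 TPM to 79.9 ± 0.389 and 55.3 ± 1.05. The arginine transporter SLC7A1 (-1.74) and SLC38A2 (-1.80) fell too, as did the glycine transporter SLC6A9, with 14.1 ± 1.13 TPM against 0.10 ± 0.04 and 0.13 ± 0.06. Of 19 glutamine and branched-chain amino acid genes, 10 fell and 4 rose (median -0.16, camera adjusted p = 0.0101, adjusted p = 0.256 with an estimated correlation). ASS1 of arginine synthesis fell by 2.47, and GPT2 (-3.12) and BCAT1 (-1.88) fell beside ASNS. These lists share 4, 1 and 1 members with the ATF4 list, and without them the median was -0.17, -0.76 and -0.14. Camera still called each of them with its preset correlation (adjusted p = 0.0103, 0.000824 and 0.0242, over the 8 lists tested this way), and none with an estimated correlation (adjusted p = 0.157, 0.203 and 0.157). Only members of the ATF4 list were removed. Targets of ATF4 outside that list may remain, so these calls cannot show a change apart from ATF4.

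Interferon-stimulated genes fell together. Of 36 tested, 35 fell, 17 of them at least 2-fold, with a median of -0.87 (camera adjusted p = 4.74e-14, adjusted p = 0.0937 with an estimated correlation), and the 1 that rose was BST2, by 0.29. IFI16, a DNA sensor, went from 165 ± 5.12 TPM to 43.2 ± 2.22 and 47.4 ± 0.177 (SD, n = 2), the antiviral GTPase MX1 from 45.6 ± 0.431 to 2.98 ± 0.417 and 8.79 ± 0.283, and XAF1 (-1.73) and IFI6 (-1.35) fell on the log2 scale. Of 24 NF-kB inflammatory genes, 14 fell and 4 rose (median -0.34, camera adjusted p = 0.0098, adjusted p = 0.329 with an estimated correlation). The chemokine CXCL10, which interferon also induces, fell by 2.26, CXCL2 by 1.44, RELB by 1.17 and CXCL8 by 0.94.

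Cytosolic ribosomal protein genes fell, and other lists of the translation machinery were called with a single guide. Of 73 cytosolic ribosomal protein genes, 70 fell and none rose (71 fell adjusted over the list alone), with a median of -0.34 (camera adjusted p = 5.33e-20, adjusted p = 0.437 with an estimated correlation). RPS27 went from 9196 ± 43.0 TPM to 6159 ± 3.75 and 6678 ± 57.7 (SD, n = 2), and RPL26 fell by 0.61, RPL4 by 0.50 and RPS15A by 0.49. Ribosomal protein genes held 23.63% and 23.71% of the TPM in the sgNS libraries and between 18.12% and 19.21% in the sgDDX6 libraries; many have pseudogene copies that can share reads with them. Over both guides, 25 of 40 MYC and ribosome biogenesis genes rose and 9 fell (median 0.16, camera adjusted p = 0.0179, adjusted p = 0.545 with an estimated correlation). This call came from sgDDX6.1, with 30 up and 3 down (median 0.35, adjusted p = 2.85e-06, adjusted p = 0.314 with an estimated correlation). With sgDDX6.2 the list did not rise against sgNS, with 13 up and 12 down (12 and 12 adjusted over the list alone, median -0.02, adjusted p = 0.94). Over both guides SRM of spermidine synthesis rose by 0.66, UTP20 by 0.76, NOP2 by 0.50 and GNL3 by 0.45. Of 70 mitochondrial ribosomal protein genes, 36 rose and 10 fell (median 0.11, camera adjusted p = 0.0159, adjusted p = 0.545 with an estimated correlation), including MRPS6 (0.74), MRPS7 (0.68), MRPL12 (0.50) and MRPL20 (0.37). This list was called with sgDDX6.1 (39 up, 8 down, median 0.17, adjusted p = 0.000338, adjusted p = 0.414 with an estimated correlation) and not with sgDDX6.2 (24 up, 12 down, median 0.04, adjusted p = 0.269). Under quantile normalization the call over both guides was lost, with a median of 0.10 and an adjusted p of 0.0986.

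Nuclear genes of the respiratory chain rose. Of 35 complex I genes, 25 rose and 3 fell (median 0.26, camera adjusted p = 0.000136, adjusted p = 0.507 with an estimated correlation). Of 39 genes of complexes II to V, 34 rose and 2 fell (35 rose adjusted over the list alone, median 0.30, camera adjusted p = 2.56e-09, adjusted p = 0.416 with an estimated correlation). NDUFS3 of complex I went from 348 ± 7.15 TPM to 491 ± 21.0 and 591 ± 0.714 (SD, n = 2), with NDUFA2 up by 0.63, NDUFA3 by 0.60 and NDUFB10 by 0.53. COX6B1 of complex IV went from 475 ± 8.56 to 697 ± 35.3 and 860 ± 13.7 TPM, with UQCR10 up by 0.68, ATP5J2 by 0.56 and ATP5A1, the ATP synthase alpha subunit, by 0.53. In the TCA cycle list, 18 of 26 genes rose and 5 fell (19 rose adjusted over the list alone, median 0.21, camera adjusted p = 0.00945, adjusted p = 0.256 with an estimated correlation). OGDH rose by 0.55 and MDH1 by 0.46, while PCK2, which takes oxaloacetate out of the cycle, fell by 2.82. Glycolysis and lactate genes were split, with 15 of 25 up and 7 down (median 0.26), and were not called (camera adjusted p = 0.0716), although they were with sgDDX6.1 (14 up, 5 down, median 0.21, adjusted p = 0.0419, adjusted p = 0.505 with an estimated correlation). With sgDDX6.2 the median was 0.32, with 14 up and 9 down (15 and 9 adjusted over the list alone, adjusted p = 0.101). Pyruvate kinase PKM rose by 0.67, PGAM1 by 0.62 and the fructose transporter SLC2A5 by 1.18, while the glucose transporter SLC2A3 fell by 1.93, from 18.8 ± 0.509 TPM to 3.69 ± 0.417 and 4.75 ± 0.156.

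Cholesterol synthesis genes had the highest list median. Of 23 tested, 21 rose and 1 fell, with a median of 0.71 (camera adjusted p = 2.44e-09, adjusted p = 0.256 with an estimated correlation). SQLE, which oxidizes squalene, went from 69.7 ± 2.86 TPM to 154 ± 4.36 and 201 ± 4.16 (SD, n = 2), and LSS rose by 1.10 and DHCR7 by 1.02.

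Among cell cycle lists, S phase genes fell and the G2 and M phase list was called with a single guide. Of 33 S phase genes, 21 fell and 2 rose (median -0.23, camera adjusted p = 0.000227, adjusted p = 0.329 with an estimated correlation). The replication licensing factor CDT1 went from 62.0 ± 3.62 TPM to 30.3 ± 1.32 and 27.1 ± 2.14 (SD, n = 2). RFC4 fell by 0.60, MCM6 by 0.56 and CDC6 by 0.55. Between the guides, 21 S phase genes were lower with sgDDX6.2 and 1 was higher (median -0.16, camera adjusted p = 5.11e-05, adjusted p = 0.324 with an estimated correlation). Of 32 G2 and M phase genes, over both guides 19 rose and 3 fell (median 0.20, camera adjusted p = 0.00205, adjusted p = 0.615 with an estimated correlation). The list was called with sgDDX6.1 (22 up, 1 down, or 23 and 1 adjusted over the list alone, median 0.33, adjusted p = 2.85e-06, adjusted p = 0.414 with an estimated correlation). It was not called with sgDDX6.2 (13 up, 7 down, median 0.05, adjusted p = 0.155). Over both guides the spindle checkpoint kinase BUB1 rose by 0.71, ANLN by 0.66, PTTG1 by 0.48 and CDC20 by 0.47.

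Among monocyte and macrophage markers, 16 of 30 rose and 8 fell over both guides (median 0.25, camera adjusted p = 0.0101, adjusted p = 0.256 with an estimated correlation). This list was called with sgDDX6.2 (21 up, 4 down, median 0.41, adjusted p = 2.89e-05, adjusted p = 0.125 with an estimated correlation) and not with sgDDX6.1 (13 up, 10 down, median 0.02, adjusted p = 0.346). The calprotectin genes S100A9 and S100A8 rose by 1.48 and 1.54, S100A9 from 2485 ± 5.28 TPM to 7405 ± 283 and 6454 ± 17.8 (SD, n = 2), and GPNMB rose by 1.80, while the transcription factor CEBPB, also in the ATF4 list, fell by 2.13. Of 21 genes of the MLL-fusion and stem cell program, 13 fell and 3 rose (median -0.21), and the list was not called (camera adjusted p = 0.0608). With sgDDX6.1 it was called (1 up, 11 down, median -0.17, adjusted p = 0.0384, adjusted p = 0.647 with an estimated correlation), and with sgDDX6.2 it was not, at a similar median (4 up, 12 down, or 5 and 12 adjusted over the list alone, median -0.20, adjusted p = 0.155). Over both guides HOXA9, a target of MLL fusions, fell by 0.57, HOXA3 by 0.73, SOCS2 by 0.39 and LMO2 by 0.30.

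Among the RNA granule lists, 10 of 18 stress granule genes fell and 1 rose (median -0.13, camera adjusted p = 0.0389, adjusted p = 0.659 with an estimated correlation). The poly(A)-binding protein PABPC1 fell by 0.66, TAF15 by 0.34 and EWSR1 by 0.30, while UBAP2L rose by 0.32. The list was called with sgDDX6.2 (13 down, 14 adjusted over the list alone, median -0.19, adjusted p = 0.0156, adjusted p = 0.727 with an estimated correlation) and not with sgDDX6.1 (8 down, 6 adjusted over the list alone, median -0.10, adjusted p = 0.184). The call over both guides was also lost without sgNS replicate 1 (median -0.12, adjusted p = 0.0758), without sgDDX6.2 replicate 1 (-0.12, 0.0514), without the limma trend (-0.13, 0.0712), and with GC trends removed (-0.09, 0.143), an alternative chosen after the data were seen. Processing body and decapping factors, a broad list that includes partners of DDX6, were not called (5 of 33 up, 13 down, median -0.03, camera adjusted p = 0.231). LSM14A, DCP1B and CNOT3 of this list were not found among the symbols. Of the tested members, ATXN2L fell by 0.80, PAN2 by 0.95 and CNOT10 by 0.38, and AGO1 rose by 0.47. The BCL2 family and apoptosis list was not called either (8 of 24 up, 9 down, median -0.03, camera adjusted p = 0.793). Here the BH3-only genes BBC3 and PMAIP1 fell by 1.41 and 1.29, while BIK, also a BH3-only gene, rose by 0.96 and BIRC5 by 0.41.

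No other list was called by camera over both guides. Their medians and adjusted p were 0.05 and 0.613 for m6A factors, 0.07 and 0.609 for immediate early genes, and 0.29 and 0.131 for granulocyte markers. They were -0.02 and 0.913 for the pentose phosphate pathway, 0.03 and 0.595 for fatty acid oxidation, 0.04 and 0.799 for fatty acid synthesis, and 0.07 and 0.793 for iron and ferroptosis. Values were -0.16 and 0.135 for the hypoxia response, 0.03 and 0.595 for autophagy and lysosome, 0.04 and 0.595 for p53 targets, 0.01 and 0.913 for drug transport and metabolism, and 0.06 and 0.29 for DDX and other RNA helicases. The replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail and so track poly(A) selection, had a median of 0.22 (13 of 31 up and 1 down, or 8 and 1 adjusted over the list alone, adjusted p = 0.0716). With a single guide, camera called the RNA helicases with sgDDX6.1 (median 0.19, adjusted p = 0.0384, adjusted p = 0.505 with an estimated correlation) and the histone genes with sgDDX6.2 (median 0.35, adjusted p = 0.0186, adjusted p = 0.237 with an estimated correlation). Median and mean had opposite signs for immediate early genes (mean -0.19), p53 targets (-0.32), fatty acid synthesis (-0.03) and drug transport (-0.05), and camera's direction was down for all of these but fatty acid synthesis.

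Markers of other cell types had few genes above the filter. Of 15 T and NK cell markers, 2 were tested, NKG7 (107 TPM in sgNS, 132 in sgDDX6.1 and 185 in sgDDX6.2) and CD8A (3.46, 0.955 and 3.21), while CD3D, CD3E and CD3G were listed at 0 in all libraries. Of 10 B cell markers, 3 were tested, with means of at most 3.35 TPM. Of 17 erythroid and megakaryocyte markers, 3 were tested, with means of at most 7.5 TPM, and of 15 epithelial and fibroblast markers, 4 were tested, of which VIM (857, 948 and 1072 TPM) is also abundant in monocytic cells and KRT18 had means of at most 19.7 TPM. Of 6 class II antigen presentation genes in the table, 3 were tested; CD74, the invariant chain, fell by 0.58, and CTSS and HLA-DMB had log2 fold changes of 0.11 and 0.43.

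Each guide was also compared with sgNS alone. Camera called 18 lists with sgDDX6.1 and 15 with sgDDX6.2, and 0 with either guide with an estimated correlation. Of the 17 lists called over both guides, 12 were called with each guide. The other 5 were called with a single guide: MYC and ribosome biogenesis, G2 and M phase, and mitochondrial ribosomal proteins with sgDDX6.1, and monocyte markers and stress granule factors with sgDDX6.2. The ATF4 list had a median log2 fold change of -2.10 with sgDDX6.1 and -2.11 with sgDDX6.2, and all 29 members fell with each (camera adjusted p = 1.15e-25 and 3.21e-23, adjusted p = 0.0824 and 0.107 with an estimated correlation). Interferon-stimulated genes had medians of -1.07 and -0.77 (camera adjusted p = 1.61e-16 and 2.53e-11, adjusted p = 0.0824 and 0.107 with an estimated correlation). Cholesterol synthesis genes had 0.61 and 0.76 (camera adjusted p = 2.33e-08 and 1.98e-10, adjusted p = 0.302 and 0.177 with an estimated correlation). By limma, sgDDX6.1 changed 6866 genes (3549 up, 3317 down; 378 at least 2-fold) and sgDDX6.2 changed 7160 (3511 up, 3649 down; 472 at least 2-fold).

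The overlap of the 2 guides was large. With both, 5331 genes passed the threshold in the same direction, 2668 up and 2663 down, and 139 in opposite directions. Independent lists would share 1117 up and 1085 down, and simulations of 3 unchanged groups of 2 libraries, of which a simulated control served both comparisons, shared a mean of 0.2 and at most 2 genes over 100 simulations. Unchanged groups yield few calls, so this small overlap was bound to follow. It does not gauge how much 2 guides with many calls would share. The fold changes had a Pearson correlation of 0.868 across genes against 0.495 simulated, a covariance of 0.197 against 0.00314, and the same sign in 82.3% against 66.7%. The sgNS libraries are too few to be split, so part of the excess may come from the shared controls.

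**Figure D3:**
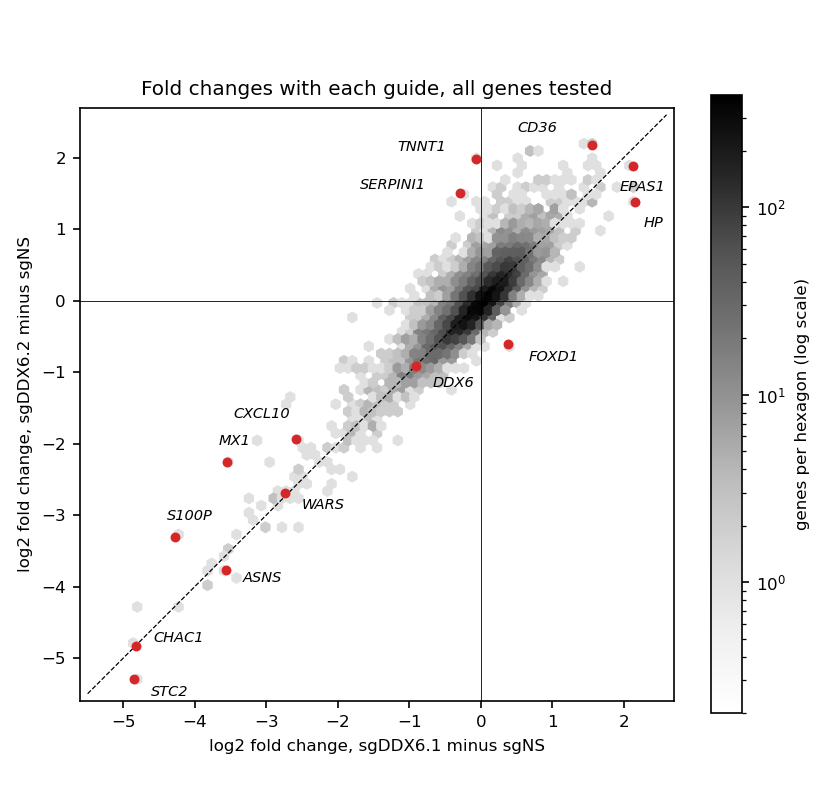
Log2 fold change against sgNS of the 11151 genes tested, sgDDX6.1 on the horizontal and sgDDX6.2 on the vertical axis; hexagons are shaded by the number of genes on a log scale and red points are named genes. Across genes r was 0.868, against a mean of 0.495 in simulations of unchanged groups that share controls. The dashed line marks equal change, and TNNT1 and SERPINI1 lie above it, higher with sgDDX6.2 by 2.04 and 1.79.

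The guides also differed from each other. TNNT1, a troponin, had 3.07 ± 0.198 TPM with sgDDX6.1 and 15.7 ± 0.544 with sgDDX6.2 (SD, n = 2), a difference of 2.04 (SE 0.08) on the log2 scale with 3.25 TPM in sgNS. SERPINI1 was higher by 1.79 with sgDDX6.2, the protease HTRA3 by 1.71, the extracellular glutathione peroxidase GPX3 by 1.41 and CD300C by 1.41. FOXD1 was lower with sgDDX6.2 by a difference of -0.99, the cationic amino acid transporter SLC7A2 by -0.81, HP by -0.78, PPP1R16B by -0.75 and VIT by -0.66. Of the 11151 genes, 3971 differed by limma, 1899 higher and 2072 lower with sgDDX6.2, and 63 at least 2-fold, all of them higher. The count fell to 2579 without sgDDX6.1 replicate 1, 2252 without sgDDX6.2 replicate 1 and 2316 without sgDDX6.2 replicate 2.

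Camera called 17 of the 34 lists between the guides and none with an estimated correlation, by which 5 passed an unadjusted p of 0.05; fry called 16. All 40 MYC and ribosome biogenesis genes were lower with sgDDX6.2 (median -0.34, camera adjusted p = 7.69e-19, adjusted p = 0.162 with an estimated correlation). So were 28 of 32 G2 and M phase genes, with none higher (30 adjusted over the list alone, median -0.23, adjusted p = 1.1e-10, adjusted p = 0.329 with an estimated correlation). Higher with sgDDX6.2 were 19 of 30 monocyte and macrophage markers against 2 lower (median 0.38, adjusted p = 2.22e-09, adjusted p = 0.144 with an estimated correlation). The same held for 23 of 36 interferon-stimulated genes against 1 lower (27 and 1 adjusted over the list alone, median 0.29, adjusted p = 2.22e-09, adjusted p = 0.144 with an estimated correlation). It also held for 22 of 37 autophagy and lysosome genes against none lower (24 and 1 adjusted over the list alone, median 0.21, adjusted p = 5.32e-09, adjusted p = 0.324 with an estimated correlation). For the ATF4 list the median difference was -0.02, with 6 members higher and 9 lower (6 and 11 adjusted over the list alone), and it was not called (adjusted p = 0.72).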

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

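The tests of the guide differences, of the culture state and of GC bias as a whole source of the calls were chosen after the results were seen, as was the list of ER chaperones. The other tests were chosen after the fall of the ATF4 list was known, and before the values they measure were seen.

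The fall of the ATF4 list, with a median log2 fold change of -2.19 and 29 of 29 members down, is the largest list change. The tables argue against scaling and transcript trends. The higher of the medians under quantile normalization and median centring was -2.187, and removing a trend on transcript GC content and length left -2.18, so neither carries it. Endoplasmic reticulum stress in the sgNS cells stays open: the ER chaperone list had a median of 0.138 where a fall was looked for, but its members went both ways, with HSPA5 up by 0.33 and CALR by 1.16, and XBP1 down (-0.94), genes chosen after their values were seen. A different nutrient or density state of the sgNS cultures remains open too: both guides gave list medians of -2.1 or lower, but all comparisons rest on the same 2 sgNS libraries, so this and an effect of DDX6 loss cannot be told apart.

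Differences between the guides form the second pattern, with 3971 genes past the threshold. If they were the same response at another strength, the difference would track the mean effect, but the correlation across these genes was 0.129. DDX6 mRNA differed by -0.008 between the guides, which argues against a different loss of the transcript; the protein was not analysed here. After GC trends were removed from each library, 94.3% of these genes were still called in the same direction, so GC bias is not the whole source. Effects of a guide outside DDX6, of the integration sites or of separate cultures stay open and could not be tested with 2 libraries per guide.

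Fold changes also rose with the GC content of the third codon position (GC3). The median log2 fold change went from -0.10 in the fifth of genes with the lowest GC3 to 0.11 in the highest, and Spearman's rho across genes was 0.156 and 0.253 with the 2 guides. Replicates of a group differed along the same axis, with a rho of up to 0.486, and slopes of 0.0152 to 0.0312 on the log2 scale per 10 points of GC3 against 0.0429 between both guides and sgNS. In all 3 groups values rose with GC3 from replicate 1 to replicate 2, and each group holds both replicate numbers. A bias shared by same-numbered libraries would therefore cancel in the group means. GC bias between single library preparations remains possible, but these values cannot decide whether it accounts for the trend. Since such a bias can hide or reverse an opposite trend, whether GC-poor mRNAs rise after DDX6 loss stays open. GC bias is not the whole source of the calls. Of the 7434 genes changed on average over both guides, 92% were still called in the same direction once GC trends were removed.

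For the remaining results, the guides differed by limma, and differences are sgDDX6.2 minus sgDDX6.1 on the log2 scale. Among genes with large changes, the difference was 0.62 for CD36, -0.59 for CHI3L1, -0.63 for CCR2, 0.75 for GPNMB, -0.78 for HP, 0.42 for SLC29A4, -0.37 for WNT7B, 0.44 for SECTM1, -0.45 for STC2, 0.52 for GDF15, -0.44 for DLX2 and 0.98 for S100P. In amino acid metabolism it was -0.13 for PSAT1, -0.22 for TRIB3, -0.21 for ASNS, -0.15 for CBS, 0.12 for ASS1, -0.30 for BCAT1, -0.52 for SLC7A5, -0.37 for SLC7A1 and -0.81 for SLC7A2. Genes chosen for their guide difference had 2.04 (TNNT1), 1.79 (SERPINI1), 1.71 (HTRA3), 1.41 (GPX3), 1.41 (CD300C), -0.99 (FOXD1), -0.75 (PPP1R16B) and -0.66 (VIT). In RNA granule lists the values were -0.18 for ATXN2L, -0.20 for AGO1 and -0.18 for PABPC1. Interferon and inflammatory genes had 1.30 (MX1), 0.35 (XAF1), 1.13 (IFI6) and 0.65 (CXCL10), and both S100A9 and S100A8 had -0.20. Ribosome and nucleolar genes had -0.21 (SRM), -0.29 (GNL3), -0.24 (NOP2), -0.43 (UTP20), 0.12 (RPS27), -0.11 (RPL4), -0.14 (MRPS7), -0.22 (MRPL12) and -0.19 (MRPL20). Respiratory and sugar metabolism genes had 0.27 (NDUFS3), 0.14 (NDUFA2), 0.19 (NDUFB10), 0.30 (COX6B1), 0.11 (ATP5A1), 0.30 (ATP5J2), 0.12 (MDH1), 0.30 (SLC2A3), 0.20 (PKM) and 0.17 (PGAM1). Cholesterol, apoptosis and cell cycle genes had 0.38 (SQLE), 0.32 (DHCR7), 0.31 (BBC3), -0.17 (BIRC5), -0.14 (RFC4), -0.32 (CDC6), -0.17 (BUB1), -0.27 (ANLN) and -0.35 (CDC20).

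Lists called by camera between the guides had median differences of 0.285 for interferon-stimulated genes, 0.096 for NF-kB inflammatory genes, 0.375 for monocyte and macrophage markers, 0.14 for fatty acid synthesis, 0.179 for cholesterol synthesis, 0.211 for autophagy and lysosome, 0.054 for p53 targets and 0.291 for replication-dependent histones. Those lower with sgDDX6.2 had -0.088 for stress granule factors, -0.344 for MYC and ribosome biogenesis, -0.055 for cytosolic and -0.12 for mitochondrial ribosomal proteins, -0.139 for serine and one-carbon metabolism, -0.187 for amino acid transporters, -0.159 for S phase, -0.233 for G2 and M phase, and -0.11 for RNA helicases. None was called with an estimated correlation, where the lowest adjusted p was 0.144. With GC trends removed, the calls of stress granule factors (median -0.105, adjusted p = 0.0567) and cytosolic ribosomal proteins (-0.058, 0.0704) between the guides were lost at medians no smaller in size, and glutamine and branched-chain amino acid genes were called (-0.119, 0.0333).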

How the results depend on the processing

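The removal of GC trends and the lists without members of the ATF4 list were chosen after the data were seen. The other alternatives were planned. Each count of changed genes stayed within 1.5 times its main value under every alternative run except these. Genes changed at least 2-fold on average over both guides numbered 380 with a pseudocount of 1, 610 with 0.1 and 209 with 5, since the pseudocount sets the fold change of low genes. Genes differing between the guides numbered 3971, and between 2252 and 4121 when a library was left out, where the lone library is assumed to vary like the other groups. Lists called numbered 17 with camera, 0 with an estimated correlation and 27 with fry, which asks another question. The estimated correlation left camera 3 degrees of freedom, with which a call is hard to reach. DDX6 fell under all of them, with log2 fold changes from -0.94 with quantile normalization to -0.79 with GC trends removed. Genes selected by the naming rule kept their direction and side of the threshold, and genes named outside it were not run. Of single lists, mitochondrial ribosomal proteins lost the call under quantile normalization (median 0.097 against 0.111), and stress granule factors under 4 alternatives besides the estimated correlation (medians of -0.13 to -0.09 against -0.13). Medians thus moved little where these calls were lost, apart from -0.09 with GC trends removed. With the replicate number as a block, 7859 genes changed on average over both guides and 4809 differed between the guides. With the 4 sgDDX6 libraries treated as a single group, 5212 genes changed against sgNS, where 7434 did in the main fit. Differences between the guides then count as spread. Deviations of same-numbered libraries correlated at 0.262, 0.098 and 0.04, all positive, and the replicate trends on GC3 had the same sign in all 3 groups. An effect shared by same-numbered libraries is therefore possible. The main fit, fixed before the data were examined, left the replicate number out. Rescaling without mitochondrial genome genes was not run, because the table used lists none. The unknown depth limits what can be said of low genes.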

Other observations

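The tests of the 4 lists in this part were chosen after the results were seen, and every gene named here was chosen after its values were seen.

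Heat shock chaperones rose with both guides. The constitutive chaperone HSPA8 went from 762 ± 8.80 TPM in sgNS to 2185 ± 18.7 with sgDDX6.1 and 1984 ± 6.34 with sgDDX6.2 (SD, n = 2), a log2 fold change of 1.45, and HSPB1 rose by 1.41, HSPH1 by 1.19, HSP90AA1 by 1.01 and DNAJB1 by 0.62. Of 26 tested members 21 rose and 2 fell, with the same counts adjusted over the list alone (median 0.39; camera adjusted p = 2.51e-07; adjusted p = 0.137 with an estimated correlation). ER chaperones were split, with 12 of 22 up and 8 down (median 0.14; camera adjusted p = 0.115), and CALR rose by 1.16 while XBP1 fell by 0.94.

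Single genes of other groups also changed. The serine protease PRTN3 rose by 1.49 and CTSG by 0.53, while the peroxidase MPO fell by 1.23. The transferrin receptor TFRC rose by 1.59 and STEAP3 by 1.23, while SLC7A11, the cystine transporter, fell by 2.37. VEGFA, in the hypoxia list, fell by 2.95. The lysozyme gene LYZ, among the most abundant transcripts, went from 9781 ± 353 TPM to 14113 ± 417 and 14704 ± 341, and SRGN rose by 1.03. MYC fell by 0.77, with 365 ± 6.86 TPM in sgNS, 254 ± 13.2 with sgDDX6.1 and 178 ± 0.01 with sgDDX6.2.

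A hypothesis is that the fall of ribosomal protein mRNAs belongs to a wider fall of mRNAs with a terminal oligopyrimidine (TOP) start, which are co-regulated with nutrient supply. A list of 17 other TOP mRNAs had a median of -0.462, and all 17 fell, also adjusted over the list alone (camera adjusted p = 1.64e-09; adjusted p = 0.0349 with an estimated correlation). EEF1A1 went from 13136 ± 146 TPM to 9181 ± 9.71 and 8305 ± 70.6 (SD, n = 2), EEF2 fell by 0.73 and TPT1 by 0.59. The result is consistent with the hypothesis, but EEF1A1 and PABPC1 had been seen before the list was written, and TPM cannot tell decay from transcription.

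Another hypothesis was that heat shock genes rise as a group beyond HSPA8 and HSPB1. The median of the other members was 0.375, against 0.391 for all 26 tested. Leaving out 2 members can move such a median only slightly, so this adds little to the list result above. HSF2 and HSPA9 fell by 0.30 and 0.73.

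A further hypothesis was that cytosolic tRNA synthetases fall for every amino acid. It was not borne out: 13 of 19 tested fell, 3 rose and 3 did not pass (median -0.92; camera adjusted p = 1.51e-06; adjusted p = 0.137 with an estimated correlation; the same counts adjusted over the list alone). WARS went from 623 ± 3.37 TPM to 92.4 ± 0.764 and 95.7 ± 2.88 (SD, n = 2), GARS fell by 1.91 and SARS by 1.56, while FARSA rose by 0.39, RARS by 0.26 and KARS by 0.13. Of these, AARS, GARS, SARS and WARS are also in the ATF4 list.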
